A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

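The series holds 4 Affymetrix expression arrays of budding yeast in log phase in rich medium, 1 array for each of 4 groups: BY4741 at 30 °C, BY4741 after 30 min at 40 °C, and the same pair for a strain labelled hsp30Δ. The deposited table, normalized by the authors, gives log2 expression values for 5802 probe sets on each array, and it holds 0 columns of other samples. Per the submitters' processing notes the values were made with GCRMA and MAS5. The notes give no versions and do not say what each tool was used for or in which order. Which probe sets the authors kept, and why, is not stated. The 4 columns share their lowest value, 1.95, and their medians lie between 11.12 and 11.19, so the values were used as deposited, with no further scaling.

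The probe annotation names genes for 5515 probe sets. Of these, 5483 pair with 1 budding yeast gene through the gene ID, and 12 symbols were updated to the current name in the reference gene table. Another 32 probe sets belong to genes of fission yeast (Schizosaccharomyces pombe), 1 of them with 2 symbols. The remaining 287 probe sets have no gene name and enter no comparison. Each gene is read from the probe set with the highest mean over the 4 arrays, which gives 5436 genes. For 45 genes there are several probe sets, and for 14 of them the probe sets differ by more than 1 log2 unit in the BY4741 heat difference. No genome build is named, so no coordinates are given. Where on the HSP30 gene its probes lie was not checked here.

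Background was set at the 95th percentile of the 32 fission yeast probe sets on each array, with the median over arrays, 1.96, as the level. Values below it were raised to it before a difference was taken, so a fold against a gene at background is a lower bound. A gene entered the comparisons if it was above background on at least 1 array, which keeps 5430 genes and leaves out 6. The number of genes above background was 5392, 5418, 5421 and 5426 on BY4741 30 °C, BY4741 40 °C and the arrays labelled hsp30Δ at 30 °C and 40 °C. The number of arrays limits the precision of every value.

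With 1 array in each group, the 4 single comparisons and the difference of the heat responses have no test. For these, genes at least 2-fold higher or lower were counted. The only test is limma (3.58.1, in R 4.3.3) with lmFit and eBayes on unfloored log2 values, with strain and temperature as additive terms. This model has 3 parameters and 1 residual degree of freedom per gene. It asks for a heat difference shared by both strains, or a strain difference shared by both temperatures. Any true difference between the strains in their heat response adds to its residual. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The agreement of 2 comparisons that share no array is given as Pearson r and Spearman rho over genes, with no p, since genes are not replicates.

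In total 30 gene lists were fixed: cytosolic chaperones, mitochondrial chaperones and protease, ER chaperones and folding enzymes, general stress genes, trehalose and glycogen, oxidative defence, proteasome, proton pump and ion transport, Hsp30 relatives and eisosome, weak acid and multidrug transporters, ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, hexose transporters, TCA cycle, respiratory chain and ATP synthase, cell wall integrity, ergosterol synthesis, fatty acid synthesis, sulfate assimilation and methionine, amino acid synthesis, phosphate starvation, iron uptake, cyclins and mitotic regulators, histones, a-specific and alpha-specific mating genes, stress transcription factors, neighbours of HSP30 on chromosome III, and genes deleted in the parent strain. For 29 of them the list median was placed among the medians of 10000 random lists of the same size, matched on mean level in 10 bins. A list outside the central 95% of these is described as outside the random range, which is a description of these arrays and not a p. By chance 1.45 of 29 lists would lie outside it in each comparison, and the lists share regulation and genes of like level, so they are not independent. Some list members were not used here, among them ENA1, AZR1, TDH2, HXT6, PHO12, HHF2, YCR022C, LEU2 and URA3, which have no gene value in the table used. Medians of the strain difference over each chromosome were placed among 2000 random sets in the same way.

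Named genes follow a fixed rule: the 8 highest and 8 lowest genes of each strain comparison, the 6 highest and 6 lowest of the difference of the heat responses, up to 10 genes past each test, 9 genes always named (HSP30, PMA1, LEU2, URA3, MET17, HIS3, HSF1, MSN2 and MSN4) and up to 4 members of each list, those with the largest difference. All 11 genes past the strain test are named, 1 more than this rule gives, which was decided after the result was seen. The groups, comparisons, tests, lists and naming rule, and most alternatives, were chosen before the data were examined. Chosen after values had been seen were a list of 14 glucose-repressed genes, a floor of 6 log2 units, a filter on a mean level above 6, the 2 diagonal pairs of arrays, counts of genes 4-fold apart at both temperatures, list medians without probe sets that carry a suffix for shared sequence, and the naming of HSP26 and HSP12.

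The limma test was tested on simulated data built from the fitted spread of 5430 genes, with 200 changed genes in 20 simulations. For the heat term 0.8%, 9.3%, 44% and 92.8% of genes changed by 1, 2, 3 and 5 log2 units were recovered, and for the strain term 0.6%, 8.7%, 41.2% and 90%. The median share of calls that were false was 9.14% for heat and 13.8% for strain, above the 5% the threshold aims at, with a median of 7.5 and 11 false calls and at most 56 and 50. With 0.25 of the fitted spread, 91.7% of genes changed by 1 log2 unit were recovered for heat and 94.1% for strain.

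Alternatives were quantile normalization, median centring, the mean of a gene's probe sets, probe sets with no suffix for shared sequence, no floor or a floor at the 99th percentile (2.41), thresholds of 1.5-fold and 3-fold, other filters on dim genes, and eBayes with a trend or a robust prior. Since single arrays give no spread, an alternative counts as unchanged when a count stays within 1.5 times, a list or chromosome median within 1 SD of its random medians, a gene within 1 SD over genes of the 40 °C minus 30 °C difference between the arrays labelled hsp30Δ (times the square root of 2 for a difference of responses), HSP30 within that SD over the square root of 2, and an agreement inside its 95% interval from 1000 bootstrap draws over genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.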

Results

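HSP30, the gene whose deletion defines the second strain, gave a strong signal on all 4 arrays: 15.51 log2 units on BY4741 30 °C, 14.18 on BY4741 40 °C, and 15.18 and 15.91 on the arrays labelled hsp30Δ at 30 °C and 40 °C. HSP30 codes for a plasma membrane protein known as a negative regulator of the proton pump Pma1. Within BY4741 HSP30 was lower on the 40 °C array than on the 30 °C array, where it read above 99.3% of genes. MET17, which BY4741 lacks, was at background on every array, at 1.95, and the highest fission yeast probe set reached 2.84. HIS3, of which the parent strain may keep a part, read 12.36, 10.22, 9.95 and 10.15, and LEU2 and URA3 have no probe set here. PMA1, the plasma membrane proton pump, read 14.94, 13.87, 14.04 and 14.46. Where the HSP30 probes lie relative to the deleted part was not checked here, and a probe outside that part would check nothing. For this reason every strain direction here is given by the label of the array.

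**Figure D1:**
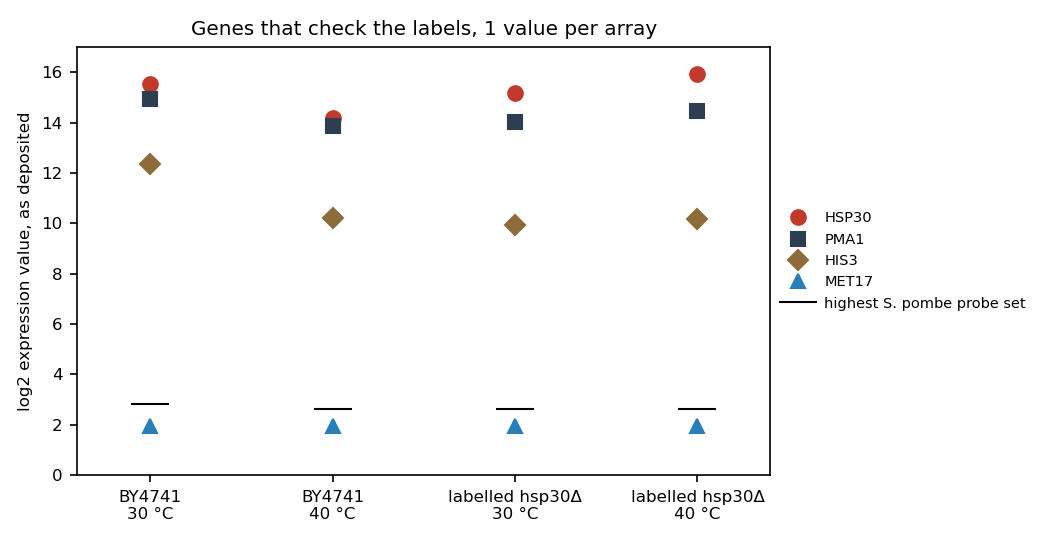
Log2 expression value (vertical axis, as deposited) of HSP30, PMA1, HIS3 and MET17 on each of the 4 arrays (horizontal axis), with the highest fission yeast probe set as a dash. Each point is 1 array. HSP30 lies between 14.18 and 15.91 on all arrays, and MET17 stays at 1.95.

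No group has a replicate. Over 5430 genes the array labelled hsp30Δ 30 °C had a Pearson r of 0.937 with BY4741 40 °C and 0.787 with BY4741 30 °C, while the 2 arrays labelled hsp30Δ had 0.980 with each other. BY4741 30 °C had 0.849 with BY4741 40 °C and 0.812 with the array labelled hsp30Δ 40 °C. Across the diagonal, 507 genes were at least 2-fold higher and 336 lower on the array labelled hsp30Δ 30 °C than on BY4741 40 °C, and 1123 were higher and 990 lower on the array labelled hsp30Δ 40 °C than on BY4741 30 °C.

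In BY4741 the genes for making ribosomes were much lower on the 40 °C array. All 41 ribosome biogenesis genes were at least 2-fold lower, with a median of -3.23 log2 units, among them SSF1 (27-fold), KRR1 (20-fold) and IMP3 (18.6-fold). Of 122 ribosomal protein genes, 114 were at least 2-fold lower, with a median of -2.03; RPL13A and RPS9B were each 13.7-fold lower. Several lists of synthesis and transport genes were lower too, while sulfate assimilation (median 0.39) and iron uptake (1.53) were not. The amino acid synthesis list had 11 of 17 members at least 2-fold lower (median -1.56; HIS1 7.12-fold, ILV3 4.78-fold), ergosterol synthesis 13 of 24 (median -1.09; ERG2 5.83-fold), and fatty acid synthesis 5 of 9 (median -1.16; ELO2 7.24-fold, FAA4 6.51-fold). Of 6 hexose transporters 3 were at least 2-fold lower and 2 were higher: HXT1, a low-affinity glucose transporter, was 16.4-fold lower, HXT2 7.21-fold lower and HXT7 higher by 0.59 log2 units, with a list median of -1.20, or -2.25 over the probe sets with no suffix for shared sequence. ER chaperones (median -0.83; LHS1 3.31-fold lower), phosphate starvation genes (-0.84; PHO84 4.29-fold lower) and glycolysis genes (-0.43; PFK2 2.66-fold lower) also lay below the random range.

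Genes of respiration, storage carbohydrates and iron uptake were higher on the BY4741 40 °C array. All 28 genes of the respiratory chain and ATP synthase were higher, 8 of them at least 2-fold, with a median of 0.85 (QCR6 3.31-fold). The TCA cycle list had 5 of 14 members at least 2-fold higher (median 0.82; SDH1 2.88-fold), and trehalose and glycogen 3 of 14 (median 0.86; GLG1 5.64-fold). Of 12 iron uptake genes 7 were at least 2-fold higher and 2 lower, with a median of 1.53 (FIT2 5.09-fold, SIT1 4.31-fold).

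HSP26, a small heat shock protein, read 15.89 on BY4741 30 °C and 16.11 on BY4741 40 °C, and HSP12 15.86 and 16.04, close to the highest value of each array, 16.01 and 16.11. Cytosolic chaperones had a median of 0.34, inside the random range, with 1 of 20 members at least 2-fold higher: SSA3, an inducible Hsp70, went from 11.23 to 15.12, a 14.9-fold difference. General stress genes were all 20 higher, 6 at least 2-fold, with a median of 0.67, inside the random range (RTN2 4.20-fold, CTT1 2.28-fold). On BY4741 30 °C the median level was already 14.97 for cytosolic chaperones and 14.89 for general stress genes. With a highest value of 16.01 on that array, this limits the rise that could be read for members near that value. It does not cover chaperones that had room to rise and were not 2-fold higher. CUR1 read 10.67 and 10.97 on BY4741 at 30 °C and 40 °C, AHA1 13.56 and 13.38, and HCH1 13.83 and 13.14. Of 20 chaperones, 13 were higher at 40 °C and 7 lower. HSF1, the heat shock factor gene, was 2.15-fold higher, MSN4 read 12.31 and 13.35, and MSN2 11.13 and 11.04.

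Of 5430 genes, 1027 were at least 2-fold higher and 1021 lower on BY4741 40 °C than on BY4741 30 °C, 37.7% in all (1005 and 1008 under quantile normalization), and 13 of 29 lists lay outside the random range. The other lists lay inside it: oxidative defence (0.63; CTA1, the peroxisomal catalase, 21.8-fold higher), proteasome (0.52), Hsp30 relatives and eisosome (0.54), mitochondrial chaperones (0.44), stress transcription factors (0.43), weak acid and multidrug transporters (0.43), sulfate assimilation (0.39; MET28 10.8-fold higher), histones (0.26), proton pump and ion transport (-0.12), cell wall integrity (-0.13), neighbours of HSP30 (-0.11), cyclins (-0.79), a-specific mating genes (-0.13) and alpha-specific mating genes (0.89).

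On the arrays labelled hsp30Δ few genes differed between 30 °C and 40 °C. Ergosterol synthesis genes were higher on the 40 °C array, 22 of 24, with a median of 0.43 and only ERG5 (2.06-fold) past 2-fold. All 9 fatty acid synthesis genes were higher (median 0.37), as were all 6 a-specific mating genes (median 0.76; AGA2 2.20-fold, MFA1 2.17-fold). HXT3 (2.38-fold) and HXT2 (2.36-fold) were higher and HXT5 3.84-fold lower, with a hexose transporter median of 0.48, or 0.95 over the probe sets with no suffix for shared sequence. Proteasome genes (0.23), glycolysis genes (0.22) and cyclins (0.36; PCL1 3.02-fold higher) also lay above the random range. Weak acid and multidrug transporters (-0.45; PDR10 1.97-fold lower), the respiratory chain (-0.18) and stress transcription factors (-0.22; MSN2 from 12.07 to 11.35) lay below it. Ribosomal proteins (-0.01), ribosome biogenesis (0.10), cytosolic chaperones (-0.02) and general stress genes (-0.02) lay inside it. The chaperone list had a median level of 15.71 on both arrays, close to their highest values, 16.16 and 16.19. In all, 88 genes were at least 2-fold higher and 85 lower, 3.19% of 5430, or 100 and 116 under quantile normalization.

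The heat responses of the 2 strain labels had a Pearson r of -0.14 and a Spearman rho of -0.19 over genes, and 42.7% of genes had the same sign. Among genes above the median level the Pearson r was -0.34. YFR057W, an uncharacterized reading frame, had the highest difference of responses, 9.48 log2 units: it read 7.21 and 2.92 on BY4741 at 30 °C and 40 °C, and 2.28 and 7.46 on the arrays labelled hsp30Δ, the 2.28 being under the highest fission yeast probe set of that array, 2.61, so that the size is not exact. The next were YVH1 (7.54), TRM11 (6.49), PPT1 (5.88), AAH1 (5.68) and RIX1 (5.61), which were high on BY4741 30 °C alone. On the array labelled hsp30Δ 30 °C YVH1 (2.89), TRM11 (3.27) and RIX1 (2.88) read close to 2.61, so their sizes are not exact either. The lowest were PCK1 (-7.08), the gluconeogenic PEP carboxykinase, YIG1 (-6.61), FAT3 (-6.57), the mitochondrial carrier SFC1 (-6.57), YDL218W (-6.37) and the lactate transporter JEN1 (-6.27). Over lists, ribosome biogenesis had a median of 3.39 and ribosomal proteins 1.98. The medians of these lists were -3.23 and -2.03 for heat in BY4741, and 0.10 and -0.01 on the arrays labelled hsp30Δ. The differences thus restate the BY4741 values and are no separate evidence. At least 2-fold apart were 1181 genes upward and 1227 downward, and this difference has no test.

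**Figure D2:**
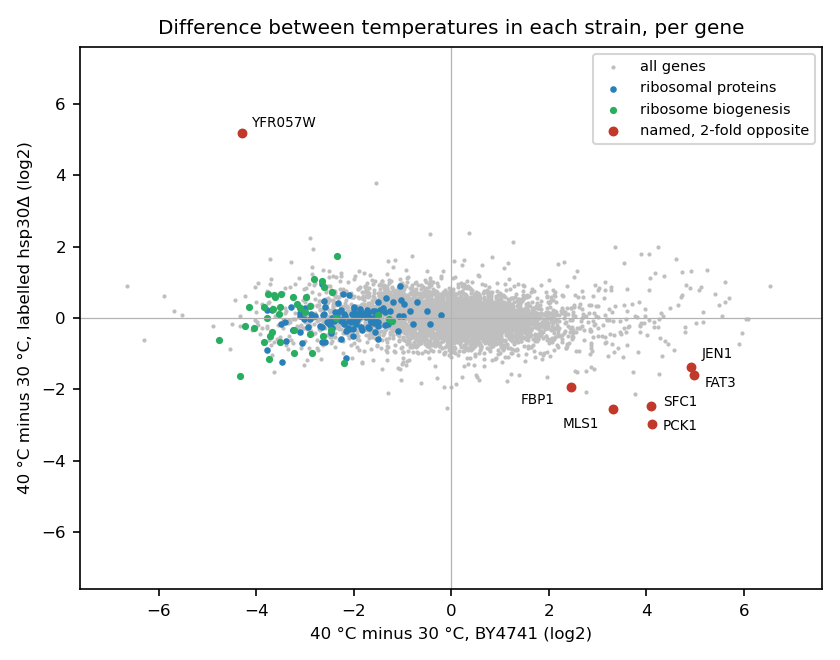
Log2 difference between 40 °C and 30 °C for each gene in BY4741 (horizontal axis) and on the arrays labelled hsp30Δ (vertical axis), from 1 array per group. The cloud is wide along the BY4741 axis and narrow along the other, with a Pearson r of -0.14.

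Tested over both strain labels, no gene passed for heat. The smallest adjusted p was 0.998, and 52 genes were higher and 57 lower at an unadjusted p under 0.05. No gene list held a member that passed when adjusted over the list alone. On simulated data with the fitted spread, which holds any difference between the 2 heat responses, this test recovered 44% of genes changed by 3 log2 units, and with 0.25 of that spread 99.9%.

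At 30 °C the genes for making ribosomes were much lower on the array labelled hsp30Δ than on BY4741. Of 41 ribosome biogenesis genes 40 were at least 2-fold lower (median -3.35; DBP9 28.9-fold, SSF1 26.5-fold), and of 122 ribosomal protein genes 118 (median -2.22; RPS0B 24.7-fold, RPS0A 23.6-fold). Ergosterol synthesis (16 of 24 at least 2-fold lower, median -1.54; ERG10 7.29-fold) and fatty acid synthesis (5 of 9, median -1.10; ELO2 11.2-fold) were lower as well. Of 6 hexose transporters 3 were at least 2-fold lower (HXT1 16.5-fold, HXT2 14.1-fold, HXT3 6.81-fold) and 2 were higher (HXT7 1.48-fold, HXT5 from 11.46 to 11.88), with a median of -1.56, or -2.77 over the probe sets with no suffix. The amino acid synthesis list had a median of -1.61, with ILV3 8.65-fold lower, while ARG3, the ornithine carbamoyltransferase, was 28.7-fold higher. Phosphate starvation genes (-0.88; PHO84 4.14-fold lower) and glycolysis genes (-0.42; HXK2 2.77-fold lower) lay below the random range too.

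All 20 cytosolic chaperones were higher on the array labelled hsp30Δ 30 °C, with a median of 0.83: SSA3 20.2-fold, CUR1 15.4-fold and AHA1 3.13-fold. Sulfate assimilation and methionine genes had 10 of 16 members at least 2-fold higher and 1 at least 2-fold lower (median 1.38; MET28 24.1-fold, MET2 15.8-fold higher). Iron uptake had 9 of 12 higher and 1 lower by that bound (median 1.58; FRE3 7.32-fold higher). Weak acid and multidrug transporters had 5 of 8 at least 2-fold higher (median 1.82; PDR10 4.16-fold, TPO1 4.06-fold), and trehalose and glycogen 7 of 14 (median 0.96; GLG1 5.34-fold), with 0 that much lower in both. Single genes with the largest differences upward included SIP4, a transcriptional activator of gluconeogenic genes (269-fold), and YOR032W-A (136-fold). The others read no higher on BY4741 30 °C than the highest fission yeast probe set, 2.84, and have no exact fold: OSW1, a spore wall gene (10.25 against 2.16), YML054C-A (9.67 against 1.95), YBR182C-A (9.46 against 2.09), ECM12 (9.51 against 2.27), YAL064W (9.75 against 2.79) and YDL114W (9.62 against 2.68). Those downward were YVH1 (130-fold), RIX1 (110-fold), AAH1 (91.3-fold), TRM11 (65.6-fold), PPT1 (58.2-fold), ARO4 (46.3-fold), NSA2 (43.7-fold) and YFR057W (2.28 against 7.21, with no exact fold). On the array labelled hsp30Δ 30 °C YVH1 (2.89), RIX1 (2.88) and TRM11 (3.27) read close to its highest fission yeast probe set, 2.61. Their folds are thus not exact sizes either.

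In all, 1262 genes were at least 2-fold higher and 1160 lower on the array labelled hsp30Δ at 30 °C, 44.6% of 5430. This comparison and the heat comparison in BY4741 subtract the same BY4741 30 °C array, so their likeness is no separate evidence. Lists inside the random range were general stress genes (0.60), respiratory chain (0.62), TCA cycle (0.47), oxidative defence (0.42; SRX1 16.8-fold higher), mitochondrial chaperones (0.63), stress transcription factors (0.86; HSF1 2.87-fold higher), ER chaperones (-0.72), Hsp30 relatives (0.53), proteasome (-0.12), proton pump and ion transport (-0.03), cell wall integrity (-0.31), cyclins (-0.65), histones (0.10), a-specific mating genes (-0.80), alpha-specific mating genes (0.63, but -0.66 under quantile normalization) and neighbours of HSP30 (-0.37), of which HTL1 read 7.90 on BY4741 and 5.77 on the array labelled hsp30Δ.

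At 40 °C the cytosolic chaperones were again higher on the array labelled hsp30Δ, 18 of 20 with a median of 0.36: CUR1 12.5-fold, HCH1 3.76-fold and AHA1 3.55-fold. Weak acid and multidrug transporters (median 0.73; TPO1 2.77-fold, PDR12 2.48-fold), sulfate assimilation genes (0.45; MET14 4.98-fold), amino acid synthesis genes (0.33; ARG3 97.6-fold) and proton pump and ion transport genes (0.33; PMA1 higher by 0.59 log2 units) lay above the random range. Proteasome genes were lower, 30 of 31 with a median of -0.40 and none past 2-fold, as were 26 of 28 respiratory chain genes (median -0.37; COX9 2.02-fold) and 100 of 122 ribosomal protein genes (median -0.26; RPL22A 4.41-fold). Ribosome biogenesis genes had a median of -0.05, or -0.32 under quantile normalization. The largest differences upward were YBR182C-A (113-fold), ARG3, OSW1 (75.1-fold), YML054C-A (69.4-fold), BSC1 (8.07 against 2.39, with no exact fold), YPR015C (43.5-fold), TAD2 (38.9-fold) and PAC1 (35.9-fold). On BY4741 40 °C YBR182C-A (3.02), OSW1 (3.12) and YML054C-A (3.12) read close to the highest fission yeast probe set, 2.61, so their folds are not exact sizes. The largest differences downward were PCK1 (11.1-fold), SFC1 (6.84-fold), MLS1 (5.89-fold), ICY1 (5.33-fold), FBP1 (5.12-fold), MXR2 (4.67-fold), AQY1 (4.56-fold) and RPL22A. PCK1, MLS1 and FBP1 code for enzymes of gluconeogenesis and the glyoxylate cycle.

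In all, 364 genes were at least 2-fold higher and 195 lower at 40 °C, 10.3% of 5430. The split was 65.1% upward as deposited and 53.5% upward (323 and 281) under quantile normalization. The strain differences at 30 °C and 40 °C had a Pearson r of 0.36 and a Spearman rho of 0.28 over genes.

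**Figure D3:**
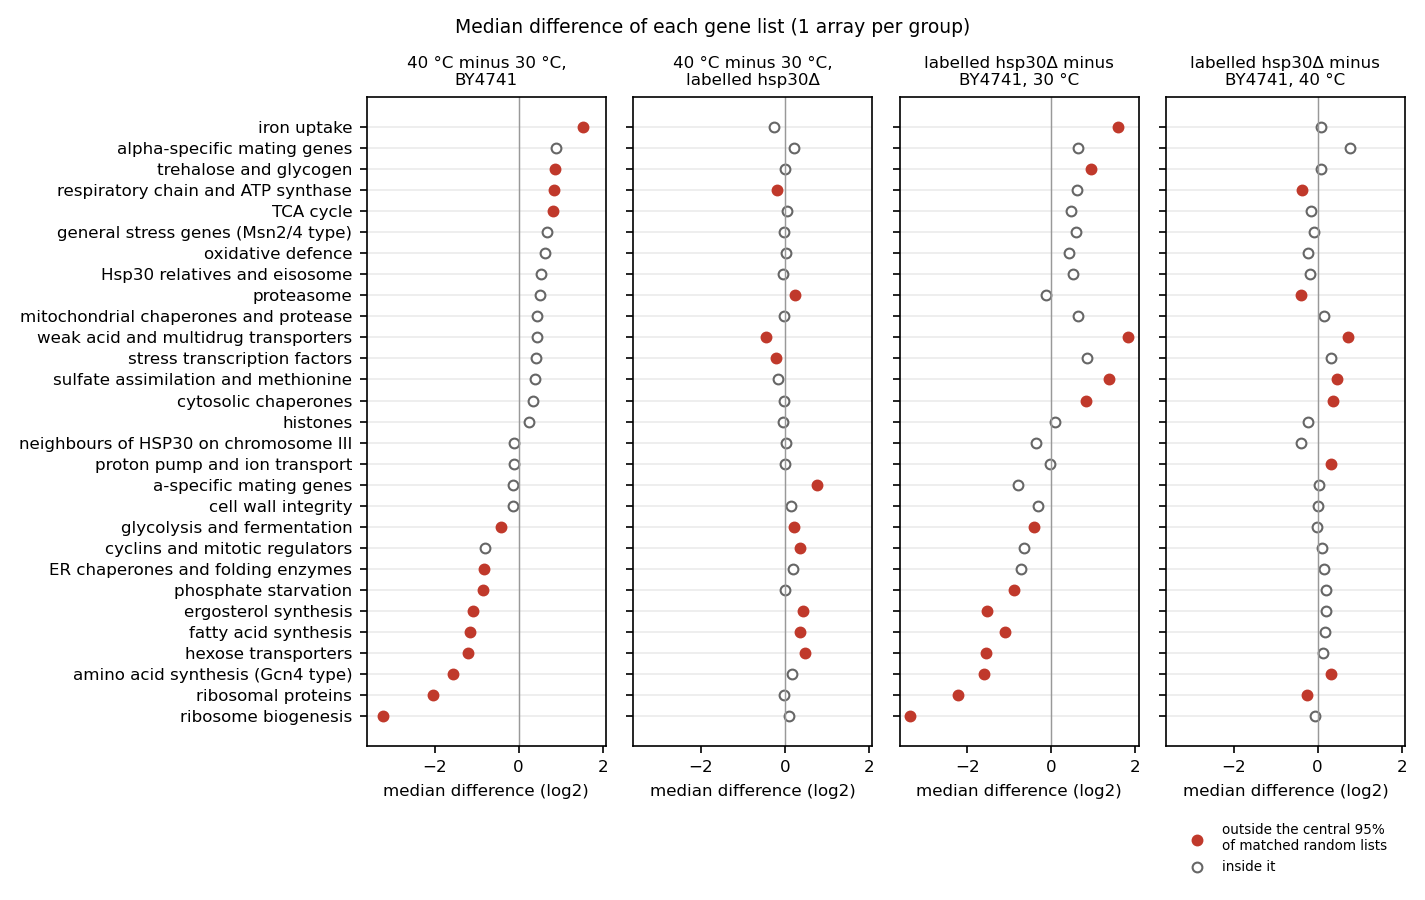
Median log2 difference (horizontal axis) of each gene list in the 4 comparisons of single arrays. Filled points lie outside the central 95% of random lists; ribosome biogenesis is at -3.23 for heat in BY4741 and at -3.35 for the strain labels at 30 °C, against -0.05 at 40 °C.

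Tested over both temperatures, 11 genes rose on the arrays labelled hsp30Δ and 0 fell, with standard errors (SE) from 1 residual degree of freedom and the prior. They were OSW1 (7.16 log2 units, SE 0.67, adjusted p 0.0237), YBR182C-A (7.10), YML054C-A (6.92), YPR015C (6.18), YOR032W-A (6.10), YDL114W (SE 0.67, adjusted p 0.0313), ARG3 (5.73, SE 0.66, adjusted p 0.0313), the tRNA deaminase gene TAD2 (5.12, SE 0.57), YDR246W-A (5.01), the dynein pathway gene PAC1 (4.88, adjusted p 0.0345) and YJR151W-A (4.63, adjusted p 0.0416). TAD2 read 8.64 and 8.49 on the BY4741 arrays and 13.60 and 13.77 on those labelled hsp30Δ, and PAC1 8.44 and 7.51 against 13.03 and 12.68. OSW1, YBR182C-A, YML054C-A, YDL114W and YJR151W-A read under 2.84, the highest fission yeast probe set, on BY4741 30 °C, and YJR151W-A also on BY4741 40 °C (1.97), so their differences are not exact sizes. Adjusted over their lists alone, CUR1, ERO1, an ER oxidase gene, and ARG3 passed. No gene passes under median centring (smallest adjusted p 0.053) or with no filter on dim genes (0.0804), while under quantile normalization 78 rose and 29 fell. On simulated data with 200 changed genes a median of 13.8% of this test's calls were false, with a median of 11 false calls and at most 50. Those runs also held many true calls, so their number of false calls cannot be set against the number called here. How many of the 11 genes are false calls is not known. The SE rest on the disagreement between the 2 temperatures and measure no spread between cultures of a strain. A difference between cultures shared by both arrays of a label would give such calls too.

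**Figure D4:**
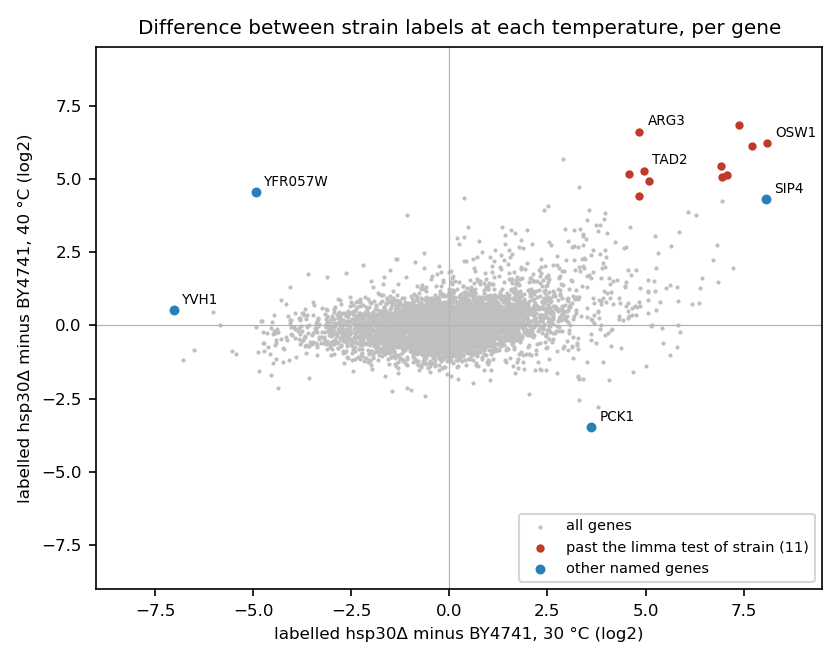
Log2 difference between the arrays labelled hsp30Δ and BY4741 for each gene at 30 °C (horizontal axis) and 40 °C (vertical axis), from 1 array per group. Genes past the strain test, such as ARG3 (4.85 and 6.61), lie at the upper right; the Pearson r is 0.36.

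By chromosome, no median of the strain difference lay outside the random range at both temperatures. Chromosome XV had medians of 0.21 at 30 °C and 0.08 at 40 °C, the second above 99.8% of random sets, and 0.04 at 40 °C under quantile normalization. Chromosome III, which carries HSP30, had 0.00 and -0.02, the second -0.10 under quantile normalization.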

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

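The tests of nonspecific background, exchanged labels, a retained HSP30 gene, scaling between arrays and loss of HSP30 were chosen only after the results were seen, as was the list of glucose-repressed genes; the bounds for cross-hybridization, glucose exhaustion and background correction were written before their values were seen.

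HSP30 gave a strong signal on the arrays labelled hsp30Δ. Nonspecific background is argued against by the highest value among genes the cells lack, 2.84. The lowest HSP30 value over all arrays, 14.18, met the bound set against an exchange of labels among the 4 arrays. That test could show an exchange between strains only if the HSP30 probes lie in the deleted part. An exchange within a strain would not show at all, so the test decides nothing here. Cells that held the HSP30 gene stay open: the lower of the 2 values lies 1.01 log2 units above the lower BY4741 value. Cross-hybridization with MRH1 or YRO2 transcripts stays open too: the 40 °C minus 30 °C difference of HSP30, 0.73, lies 0.44 from that of MRH1, inside the bound of 0.46, but 90.4% of all genes meet the same bound, so this test excludes little. Probes outside the deleted part could also give the signal and were not checked here.

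The array labelled hsp30Δ 30 °C resembles the 40 °C arrays. No scaling tried here removes the difference, since the ribosome biogenesis median is -3.35 even at its closest to 0 over the alternatives. The test of scaling decides little beyond that. Quantile normalization and median centring shift the median strain difference over all genes by only -0.02 and -0.04, so they could hardly reach the bound of -1. A culture past glucose exhaustion stays open: glucose-repressed genes had a median 2.47 higher than on BY4741 30 °C, above all random lists, but the same list was 2.53 higher on BY4741 40 °C, so this does not separate it from a heated culture. Loss of HSP30, the biological difference the labels name, cannot be told apart from a difference between cultures: HSP30 was -0.33 from BY4741 30 °C, the place of its probes is unknown here, and strain and culture coincide. An exchange of labels among the 4 arrays stays open, as does an array from outside this series: the second highest array median of ribosome biogenesis lies -3.03 from the highest, 11.52, which met the bound first set against an exchange, but exchanging the 2 BY4741 labels would leave that value as it is, so the test decides nothing.

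Many genes read low on BY4741 30 °C and higher at 40 °C. If background correction of that array were the cause, the genes 2-fold higher at 40 °C would be dim ones, but of 3 bins of genes by level the top one holds 32.5% of them and the bottom one 38.4%. Heat, which the design names, stays open as untested.

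Several heat responses went opposite ways under the 2 strain labels, which was not tested, as each group has 1 array. The difference of responses was 0.55 for glycolysis, 2.16 for hexose transporters, 1.72 for ergosterol synthesis, 1.70 for fatty acid synthesis, -1.03 for the respiratory chain and -3.19 for glucose-repressed genes. For single genes it was 9.48 for YFR057W (not an exact size, as 1 of its readings is near background), -7.08 for PCK1, -6.57 for FAT3, -6.57 for SFC1, -6.27 for JEN1, -5.86 for MLS1 and -4.38 for FBP1.

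Among 287 probe sets with no gene name, which the report leaves out, 216 read above the highest fission yeast probe set on at least 1 array. On BY4741 40 °C 67 of the 287 were at least 2-fold higher and 31 lower than on BY4741 30 °C.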

How the results depend on the processing

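The floor of 6, the filter on a mean above 6, the list medians without suffixed probe sets and the 4-fold counts were chosen only after values were seen. Of 146 alternative values of the main results 123 stayed the same, as did 472 of 480 list medians, 14 of 18 chromosome medians and 1520 of 1598 values of named genes. Part of these had little room to change. Median centring shifts all genes of an array alike, and it left all 799 values of named genes the same. Under quantile normalization 721 of 799 stayed the same, 77 moved and 1 reversed. The cause of the changes below was not tested unless given. Near-even splits turned. Heat on the arrays labelled hsp30Δ went from 88 higher and 85 lower to 100 and 116 under quantile normalization and 75 and 78 with a floor of 6. Heat in BY4741 went from 1027 and 1021 to 1005 and 1008 under quantile normalization, 1002 and 1014 without suffixed probe sets and 927 and 1015 with a floor of 6. The difference of responses went from 1181 and 1227 to 1172 and 1138 with a floor of 6. Under quantile normalization the median strain difference at 40 °C went from 0.00 to -0.04.

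A 1.5-fold threshold by its construction takes in more genes: 1800 higher for heat in BY4741, 442 higher and 423 lower for heat on the arrays labelled hsp30Δ, 858 and 822 for the labels at 40 °C, and 1926 lower for the difference of responses. A 3-fold threshold takes in fewer: 432 and 577, 20 and 23, 694 and 694 for the labels at 30 °C, 174 and 27 at 40 °C, and 709 and 578. Strain calls were 78 higher and 29 lower under quantile normalization, 0 under median centring, 0 with no filter on dim genes and 19 with a mean above 6. Among genes above the median level the agreement was -0.34 for the heat responses and 0.27 for the strain differences. MF(ALPHA)2 reversed for heat in BY4741, from 1.27 to -0.53 under quantile normalization. Genes 4-fold lower at both temperatures were 6 under quantile normalization against 1. Centring on spike-in probe sets was not run, since the table used holds none, and leaving out 1 array leaves 0 residual degrees of freedom. The number of arrays limits all of this.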

Other observations

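The set of 4-fold genes, the glucose-repressed list and the test of neighbouring genes were all chosen only after the results were seen.

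Glucose-repressed genes, chosen to leave out genes already looked at, had list medians of 10.12 and 12.28 on BY4741 at 30 °C and 40 °C, and 12.46 and 11.18 on the arrays labelled hsp30Δ. In BY4741 10 of 14 were at least 2-fold higher at 40 °C (median 2.53): ICL1, the isocitrate lyase of the glyoxylate cycle, 13.2-fold, IDP2 10.1-fold and the carnitine acetyltransferase CAT2 9.52-fold. On the arrays labelled hsp30Δ 12 of 14 were lower at 40 °C (median -0.64; YAT1 3.34-fold, POX1 2.88-fold, ICL1 2.84-fold).

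On the arrays labelled hsp30Δ 70 genes were at least 4-fold higher than BY4741 at both temperatures and 1, RPL22A (-4.36 and -2.14), was lower; under quantile normalization 57 were higher and 6 lower. The 70 hold 7 pairs of adjacent genes: YBL071C-B with KTI11, SMP1 with YBR182C-A, PRM7 with BSC1, SIP4 with ARG3, YOR008C-A with TIR4, YOR268C with PAC1, and YOR302W with CPA1. Random sets of the same size held a median of 1 and at most 6 in 10000 draws. A hypothesis is that transcription running into neighbouring genes could give such pairs. The 7 pairs exceed the bound of 3, but 4 lie on the same strand and 3 on opposite strands, so this stays open. The clause on strands was added after the pairs were seen. Whether both genes of a pair lie on a single transcript was not checked here, nor were probe sets that overlap both genes. Such pairs would be counted with no transcription running from a gene into its neighbour.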
